A study of Anguilla japonica with 6 samples.

How the data were processed

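Total RNA of female Japanese eel pituitaries was extracted with TRIzol and made into libraries with an NEBNext Ultra II RNA kit, per the labels' protocols. CASAVA 1.8 is named in the submitters' processing notes. The aligner, counter, genome build and annotation are not given in the sources used here. The deposited table holds 1 value per gene and library, which was read as FPKM from the values alone: they are not whole, their totals differ between libraries (500088 to 713023), and FPKM and RPKM cannot be told apart. The authors' normalization thus divides by gene length and library depth and corrects for no other difference between libraries.

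Of 32359 genes, 14175 carry a symbol, 16895 a LOC identifier and 1289 a Novelgene identifier, and 4858 are at 0 in every library. Whole reads were rebuilt from the values. For 25782 genes above 0 in at least 2 libraries, ratios of the values gave whole reads for 100% at a relative tolerance of 1e-10, against 5.4% of 2000 scrambled genes; a further 1719 genes were above 0 in exactly 1 library. On simulated reads the procedure returned exact reads for 99.1% of 11573 genes. Rebuilt depths were 16033675 to 19619964 reads in matured and 18206029 to 19276653 reads in pre-matured libraries, and rebuilt reads made up 99.3% to 99.6% of them. The labels name no molecular identifiers, so a read number speaks for counting error only. Mitochondrial genes such as COX1 are at 0 in all libraries, so a 0 is reported as listed and not as absence.

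The labels' age field gave the groups, 3 matured and 3 pre-matured libraries. Replicate numbers follow accession order and pair nothing. No 2 libraries were near-identical: the highest correlation was 0.947. Before the data were examined, the test, the gene lists, the rule for named genes and most alternatives were fixed. Genes with FPKM of 1 or more in at least 3 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust settings), Benjamini-Hochberg adjusted p under 0.05. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

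In simulated data for this comparison with a dispersion near 0.1, 85.9% of 191 genes changed 4-fold were recovered among 18125 genes, with 7.9% of 178 calls false. Of 195 genes changed 2-fold among 18135 genes, 0% were recovered and all 3 calls were false. With so few genes changed, the Benjamini-Hochberg threshold is stricter than in the real comparison, where 5981 of 17887 genes were called. The simulation thus does not give the power for 2-fold changes in the real data. False calls can exceed the nominal 5%.

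Gene lists (32) were matched by symbol: pituitary hormones, gonadotropin regulators, other releasing factor receptors, pituitary lineage factors, steroid synthesis, cholesterol synthesis, fatty acid synthesis, ER protein processing, translocation and N-glycosylation, ER to Golgi transport, secretory granules, cell cycle, oxidative phosphorylation, glycolysis, cytosolic ribosomal proteins, immediate early and stress genes, cAMP, calcium and MAPK signalling, thyroid hormone and retinoid signalling, IGF, insulin and leptin signalling, circadian clock, matrix remodelling and 11 lists of cell type markers. LOC identifiers could not enter a list. The ribosomal pattern also took in kinases and ribosomal protein-like genes, which were removed by name after the data were seen; the list with them is an alternative. Lists with 5 or more tested members (26) were tested with camera, preset correlation 0.01, against all other genes.

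The genes named are: all tested hormone genes and the 8 gonadotropin regulators with the smallest p; the 8 largest rises and 8 largest falls among called genes with a symbol, groups that do not overlap and a mean FPKM of at least 5; up to 3 members with the smallest p of every other list with a called member or a passed test; and the 5 genes with the highest mean. The names of 2 genes that have only a clone name are not printed. Of 17887 genes tested, 8800 had groups that do not overlap, where chance gives 10%. Near-identical paralogs can share reads, and how the authors' counting treated them is not given in the sources used here.

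Alternatives were no filter, a filter of 5 FPKM, a pseudocount of 0.1, TPM, totals without genes above 1% of a library, quantile normalization, leaving out each library, a fold of at least 2, adjusted p under 0.01, camera with estimated correlation, and fry. Median-ratio scaling, voom on rebuilt reads and removal of a length trend were added after the data were seen. Alternatives planned for a table of counts or of transcripts were not run, since the table holds neither.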

Results

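Gene expression was measured by RNA-seq in pituitaries of female Japanese eel (Anguilla japonica), a fish whose gonads mature late in life. The labels place 3 libraries in a matured group and 3 in a pre-matured group, and the series pairs short-read libraries with full-length transcript sequencing. The values are FPKM (reads scaled to gene length and library depth) for 32359 genes. Reads rebuilt from these values gave a depth of 16033675, 19619964 and 16257326 reads in matured 1, 2 and 3, and of 19276653, 18600632 and 18206029 reads in pre-matured 1, 2 and 3. The labels name no batch, and nothing beyond the sample titles says that the libraries came from separate animals, so the p-values below measure the spread between these samples. The comparison asks which genes differ between pituitaries labelled pre-matured and matured. The labels do not say whether maturation was natural or induced by hormones. An effect of such a treatment could therefore not be told apart from maturation.

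The 6 libraries separated by group. Pearson correlations across genes of log2 values were 0.920 to 0.947 between libraries of a group and 0.780 to 0.825 between libraries of different groups, over 17887 genes, which are not independent replicates. The first principal component held 63.7% of the variance and parted the groups, and the second, with 11.6%, mainly spread the pre-matured libraries. Pre-matured libraries had FPKM of 1 or more for 15708, 16770 and 16817 genes, against 17599, 18280 and 17602 in matured libraries. Ribosomal protein genes held 26.7%, 23.7% and 22.7% of the FPKM total in pre-matured libraries and 14.5%, 13.9% and 14.5% in matured ones.

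**Figure D1:**
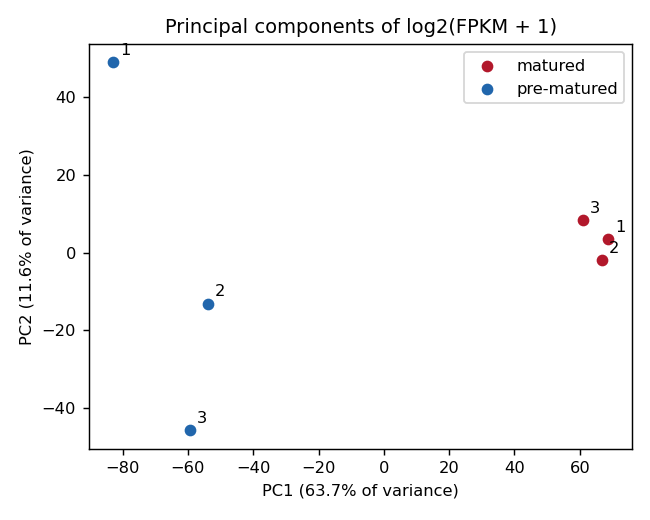
First and second principal components of log2(FPKM + 1) over 17887 genes, with the share of variance in percent on each axis. Each point is a library, numbered by replicate and coloured by group, and the first component (63.7% of variance) parts matured from pre-matured libraries.

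Of 17887 genes tested, 4184 were higher and 1797 lower in matured pituitaries (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 3103 and 1116 also changed at least 2-fold. Among genes with a symbol, from which the gene lists below were drawn, 21.9% were higher and 10.6% lower. A list whose counts lie near these shares is not set apart from other genes by them. Leaving out matured 1, 2 or 3 lowered the higher genes to 1942, 2081 and 2273 and the lower genes to 958, 1236 and 1077. The filter still asked for 3 libraries, so genes under 1 FPKM in all pre-matured libraries were then not tested (16856, 16696 and 16802 genes tested). Fewer higher genes without a matured library, here and in the lists below, can thus come from the filter. The balance of the 2 directions depended on scaling: 70.0% of calls were higher with FPKM as deposited, 85.6% after rescaling to TPM, 85.6% with totals taken without genes above 1% of a library, and 50.1% after quantile normalization. With median-ratio scaling and with voom on rebuilt reads, both chosen after the data were seen, 54.2% and 53.5% of calls were higher. The median log2 fold change of all genes was 0.23 with FPKM, 0.54 with TPM, 0.50 without genes above 1%, -0.02 with quantile normalization, 0.03 with median-ratio scaling and 0.04 with voom. Fold changes are on the scale of log2(FPKM + 1), which understates the change of weakly expressed genes.

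The gene of the luteinizing hormone beta subunit, lhb, had the largest rise among genes with a symbol. It stood at 13430, 5835 and 11134 FPKM in matured libraries and at 0.543, 0.394 and 29.8 FPKM in pre-matured ones, with 10, 7 and 518 rebuilt reads in the latter (log2 fold change 11.21 ± 1.13 SE, limma adjusted p = 0.00128). Growth hormone, gh1, rose from 2518 ± 1037 to 21661 ± 10574 FPKM (SD, n = 3 per group; limma adjusted p = 0.00479). These were 2 of the 5 hormone genes tested, and the count was also 2 adjusted over the list alone. The follicle-stimulating hormone beta subunit, fshb, did not pass (limma adjusted p = 0.778): it stood at 4.44, 514 and 0.899 FPKM in matured libraries and 7.25, 4.71 and 21.2 FPKM in pre-matured ones. Without matured 2 its log2 fold change went from 0.78 to -1.66, with a limma adjusted p of 0.126. Somatolactin, smtlb, was at 1342, 1244 and 4698 FPKM in matured and 68.9, 1757 and 28.1 FPKM in pre-matured libraries, and passed without pre-matured 2 (limma adjusted p = 0.0823 with all libraries, 0.00439 without it) and with quantile normalization (limma adjusted p = 0.0433). Proopiomelanocortin, pomca, was at 19.2 ± 8.20 against 23.2 ± 6.12 FPKM and did not pass (SD, n = 3; limma adjusted p = 0.497).

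**Figure D2:**
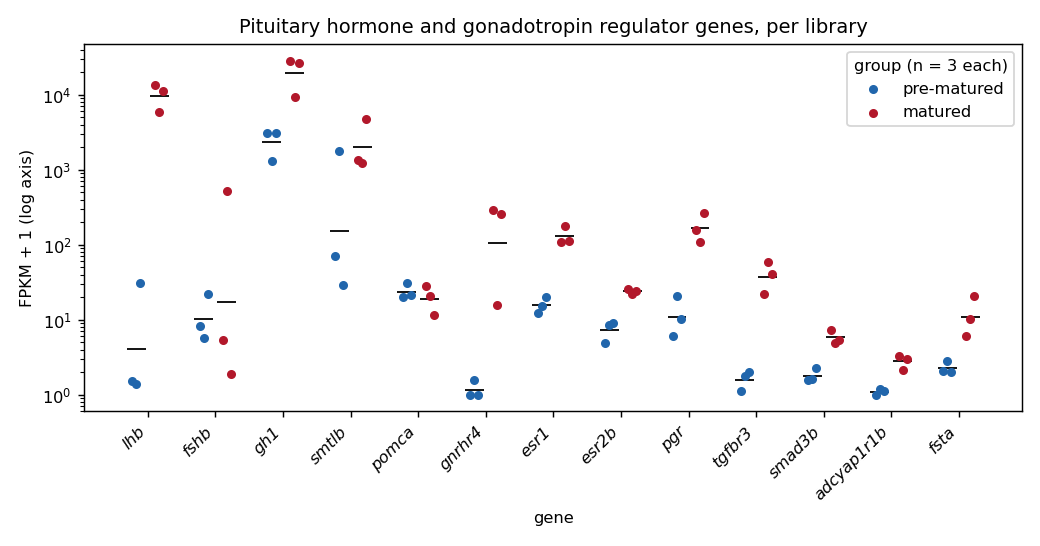
FPKM + 1 on a log axis for hormone and gonadotropin regulator genes. Each point is a library, blue for pre-matured and red for matured (n = 3 each), and black lines are means of the log values; lhb lies at 5835 FPKM or more in matured libraries and at 29.8 FPKM or less in pre-matured ones.

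Of 20 gonadotropin regulators tested, 9 rose and 1 fell, and the counts were the same adjusted over the list alone. Without matured 1, 2 or 3, which leaves fewer genes past the filter, 6, 5 and 6 rose. The estrogen receptor gene esr1 rose from 14.9 ± 3.99 to 132 ± 37.6 FPKM, esr2b from 6.50 ± 2.22 to 23.0 ± 1.62 FPKM and the progesterone receptor gene pgr from 11.3 ± 7.51 to 176 ± 80.4 FPKM (SD, n = 3; limma adjusted p = 0.000761, 0.00285 and 0.00174). The gonadotropin-releasing hormone receptor gene gnrhr4 rose (limma adjusted p = 0.00450), with 287, 14.5 and 254 FPKM in matured libraries against 0.582 FPKM in pre-matured 2, while pre-matured 1 and 3 are listed at 0. Its call was lost with voom on rebuilt reads (adjusted p = 0.242), where the fitted log2 fold change was 11.22 against 6.49. Of the other members named, tgfbr3, a TGF-beta co-receptor gene, rose with a log2 fold change of 4.57 ± 0.39, smad3b, an intracellular transducer, with 1.70 ± 0.29, and fsta, the activin-binding follistatin, with 2.25 ± 0.43 (SE; limma adjusted p = 0.000696, 0.00382 and 0.00616). The member that fell was pgrmc2 (log2 fold change -0.87, limma adjusted p = 0.00950), chosen after its values were seen. With TPM 11 members rose and 0 fell, and with totals taken without genes above 1% 12 and 0, so its call was lost in both. The PACAP receptor gene adcyap1r1b rose at low levels, with 2.34, 1.14 and 2.04 FPKM in matured libraries against 0.198 and 0.129 FPKM in pre-matured 2 and 3 and a listed 0 in pre-matured 1 (limma adjusted p = 0.00607). The list as a whole was higher by camera with a preset correlation (adjusted p = 0.0117), and not with an estimated correlation (adjusted p = 0.742).

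Receptors for other releasing factors moved the same way, with 8 of 12 higher and 0 lower, or 8 and 1 adjusted over the list alone. Without matured 1 or matured 2, 5 of the 10 still tested rose. The ghrelin receptor gene ghsra rose with a log2 fold change of 3.14 ± 0.31, the GABA-B receptor gene gabbr1b with 2.24 ± 0.30 and the serotonin receptor gene htr1b with 1.65 ± 0.24 (SE; limma adjusted p = 0.000902, 0.00184 and 0.00248). This list passed camera with a preset correlation (adjusted p = 0.0317), but not with an estimated correlation (adjusted p = 0.742), after rescaling to TPM (adjusted p = 0.0583), with totals taken without genes above 1% (adjusted p = 0.0787), after removal of a length trend (adjusted p = 0.0563), or without matured 1 or pre-matured 2 (adjusted p = 0.0651 and 0.0883). Its median log2 fold change was 1.66, and between 1.63 and 2.18 in the settings with another scaling or 1 library less named here.

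The other large rises among named genes were of cltrn (collectrin, log2 fold change 6.24), a gene with a clone name only (5.67), slc17a5 (the lysosomal sialic acid transporter, 5.41), fam20a (5.16), hsd17b3 (a 17-beta-hydroxysteroid dehydrogenase, from 4.16 ± 3.88 to 135 ± 39.5 FPKM; SD, n = 3) and nots, all with limma adjusted p between 0.000284 and 0.0101. Nots was at 121, 4.36 and 41.7 FPKM in matured libraries and is listed at 0 in all pre-matured ones. Its call was lost with voom on rebuilt reads (adjusted p = 0.324), where the fitted log2 fold change was 10.32 against 4.92. The largest falls were of fosl1a, an AP-1 transcription factor gene, from 30.5 ± 5.66 to 1.14 ± 0.106 FPKM, phlda2 from 60.6 ± 49.6 to 2.76 ± 1.27 FPKM, and alpk2 from 80.8 ± 52.9 to 5.55 ± 0.774 FPKM (SD, n = 3; limma adjusted p = 0.000284, 0.00244 and 0.00162). The arginase gene arg2 fell from 198 ± 59.0 to 20.6 ± 14.96 FPKM (limma adjusted p = 0.00223, SD, n = 3). A gene with a clone name only, ca6 (a carbonic anhydrase), kncn and c16h15orf48 fell with log2 fold changes of -3.44, -3.35, -3.24 and -3.10. The call of c16h15orf48 was lost when any matured library was left out, with limma adjusted p between 0.125 and 0.147, with TPM, no filter and a length trend removed (0.0501, 0.0693 and 0.0679), and with voom, as was that of ca6 with voom (adjusted p = 0.218 and 0.068; log2 fold change -4.84 and -5.45).

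Among pituitary lineage factors 8 of 25 rose and 1 fell, the same adjusted over the list alone; without matured 1, 2 or 3, 4, 4 and 5 rose. With median-ratio scaling and voom 6 rose and 2 fell. The pituitary transcription factor gene pax7b rose from 0.465 ± 0.618 to 11.8 ± 5.04 FPKM, eya1 from 23.5 ± 7.54 to 77.3 ± 21.4 FPKM, and eya3 from 0.278 ± 0.171 to 2.46 ± 0.0637 FPKM (SD, n = 3; limma adjusted p = 0.00142, 0.00417 and 0.00326). In steroid synthesis and metabolism 3 of 16 rose and 2 fell, again the same adjusted over the list alone, and 1 fell without matured 1 or any 1 of the pre-matured libraries. With TPM and without genes above 1% 5 rose and 1 fell. Hsd20b2 rose with a log2 fold change of 1.58 and tspo, the mitochondrial translocator protein gene, fell with -1.86. In cholesterol synthesis and uptake 8 of 25 rose and 0 fell, or 8 and 0 adjusted over the list alone, and 4, 5 and 5 rose without matured 1, 2 or 3. With quantile normalization and median-ratio scaling 5 rose and 2 fell, and with voom 4 rose and 1 fell. The higher genes included stard4 (log2 fold change 1.70), srebf2 (1.02), which encodes a sterol-regulated transcription factor, and the lipoprotein receptor gene scarb1 (1.14). In fatty acid synthesis 4 of 19 rose and 1 fell, the same adjusted over the list alone. Without any 1 of the matured libraries 2 of the 17 genes still tested rose, and gpam was not past the filter. Gpam and agpat2, acyltransferase genes of glycerolipid synthesis, rose with log2 fold changes of 1.67 and 1.33, and elovl1b, a fatty acid elongase gene, fell from 169 ± 11.6 to 71.1 ± 4.11 FPKM (SD, n = 3; limma adjusted p = 0.00208).

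Genes of the secretory route went both ways. In translocation and N-glycosylation 14 of 46 fell and 3 rose, the same adjusted over the list alone, and 8 fell without matured 1 or matured 2; 0 to 2 rose without any 1 library. With TPM 6 rose and 9 fell, and with voom 0 and 18. The translocon gene sec61b fell from 113 ± 10.9 to 40.5 ± 3.08 FPKM, alg5 from 34.8 ± 1.25 to 13.8 ± 2.34 FPKM and mogs from 40.1 ± 15.1 to 10.6 ± 0.909 FPKM (SD, n = 3; limma adjusted p = 0.00147, 0.00274 and 0.00298). This list was lower by camera with a preset correlation (adjusted p = 0.000147), and not with an estimated correlation (adjusted p = 0.742). Its median log2 fold change was -0.29, and 0.033 after rescaling to TPM and 0.036 with totals taken without genes above 1%, which raise the median of all genes too. Relative to that median it was -0.52, -0.51 and -0.47, and the list passed camera with a preset correlation under both (adjusted p = 0.00180 and 0.00213). In ER to Golgi transport 7 of 40 rose and 11 fell, or 13 and 12 adjusted over the list alone, and after rescaling to TPM 16 rose and 6 fell, against 3 and 14 with voom. Without matured 1, 3 rose and 8 fell, without matured 2, 7 rose and 6 fell, and without matured 3, 5 rose and 7 fell. Its median and mean log2 fold change were 0.10 and 0.023 while camera, which compares with all other genes, pointed down, without passing (adjusted p = 0.379). Relative to all genes its median was -0.13. The ER to Golgi members arcn1a and uso1 rose with log2 fold changes of 1.21 and 1.67, and sec13 fell with -1.21. In ER protein processing 8 of 39 rose and 3 fell, the same adjusted over the list alone (3 rose without matured 1 or pre-matured 1, and 5 and 4 without matured 2 and 3). With TPM 12 rose and 2 fell, without genes above 1% 13 and 2, with median-ratio scaling 4 and 4, and with voom 5 and 4. The oxidoreductase gene ero1b rose (log2 fold change 1.71), and its paralog ero1a (-1.56) and txndc11 (-1.27) fell. Here too the median and mean, 0.054 and 0.15, lay above 0 while camera pointed down (adjusted p = 0.658), and the median relative to all genes was -0.18. Of secretory granule and hormone processing genes 11 of 39 rose and 5 fell, the same adjusted over the list alone, and 7 and 6 rose without matured 1 and 2. The lower ones numbered 2 without any 1 of the matured libraries and 3 without pre-matured 1. With totals taken without genes above 1% 17 rose and 2 fell, and with TPM 14 and 1. The granin gene scg3 rose from 1959 ± 514 to 18025 ± 8486 FPKM, and the exocytosis genes syt7a and unc13a rose with log2 fold changes of 3.21 and 1.86 (SD, n = 3; limma adjusted p = 0.00142, 0.000902 and 0.00198).

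Cytosolic ribosomal protein genes were lower in matured pituitaries: 52 of 62 fell and 0 rose, or 58 and 0 adjusted over the list alone, with a median log2 fold change of -0.99. The difference from the median of all genes was -1.22, and -0.321 with quantile normalization. The median was negative under each scaling, from -0.35 with quantile normalization, where 26 fell and 3 rose, to -1.26 with voom. Rpl6 fell from 4452 ± 674 to 654 ± 77.5 FPKM, rpl17 from 5771 ± 900.4 to 1123 ± 98.1 FPKM and rpl13 from 3476 ± 536 to 718 ± 89.9 FPKM (SD, n = 3; limma adjusted p = 0.000324, 0.000537 and 0.000653). The list passed camera with a preset correlation (adjusted p = 2.10e-27), and not with an estimated correlation (adjusted p = 0.742). Glycolysis genes were also lower, with 6 of 17 lower and 0 higher, or 8 and 0 adjusted over the list alone, and 10 and 0 with median-ratio scaling and voom. With TPM 6 fell and 1 rose, and with totals taken without genes above 1% 6 and 2. The median log2 fold change was -0.60 with FPKM and -0.28 and -0.27 under these 2 scalings. Relative to the median of all genes it was -0.83, -0.82 and -0.78. The enolase gene eno1a fell from 1337 ± 235 to 273 ± 48.7 FPKM, the aldolase gene aldoaa from 328 ± 84.4 to 80.5 ± 4.36 FPKM and gapdhs from 814 ± 92.3 to 319 ± 47.0 FPKM (SD, n = 3; limma adjusted p = 0.000902, 0.00132 and 0.00208). Glycolysis passed camera with a preset correlation (adjusted p = 0.000135), and not with an estimated correlation (adjusted p = 0.742).

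Nuclear genes of oxidative phosphorylation split, with 10 of 47 lower and 3 higher, the same adjusted over the list alone. Without matured 1 or 2, 4 and 6 fell, and 1 rose without matured 2 or 3. With median-ratio scaling 1 rose and 15 fell, and with voom 1 and 14. The complex I genes ndufb7 and ndufa9a fell with log2 fold changes of -1.48 and -1.28, and ndufb5, also of complex I, rose with 1.27. The list was lower by camera with a preset correlation (adjusted p = 0.00110) and not with an estimated correlation (adjusted p = 0.867) or with quantile normalization (adjusted p = 0.0852). Its median was -0.22, or -0.46 relative to all genes. After rescaling to TPM, where 8 rose and 5 fell, and with totals taken without genes above 1% it was 0.10 and 0.11, or -0.44 and -0.40 relative to all genes, and the list passed camera with a preset correlation (adjusted p = 0.0294 and 0.0359). After removal of a length trend the median was 0.095, or -0.16 relative to all genes, and camera did not pass (adjusted p = 0.606). Of 34 cell cycle genes 6 fell and 1 rose, or 1 and 1 adjusted over the list alone, and 1 to 3 fell when any library was left out. With quantile normalization 11 fell, and with TPM 2 fell and 2 rose. Dnmt1 and mad2l1 fell with log2 fold changes of -1.19 and -1.19, and the replication gene mcm3 rose from 4.45 ± 2.33 to 23.0 ± 5.73 FPKM (SD, n = 3; limma adjusted p = 0.00279). The call of mad2l1 was lost without any 1 of the matured libraries (limma adjusted p between 0.0638 and 0.0788) and with voom (0.0742). The cell cycle list passed camera with a preset correlation (adjusted p = 0.0317), but not with an estimated correlation (adjusted p = 0.742) or with the stricter filter, voom or removal of a length trend (adjusted p = 0.254, 0.107 and 0.174), and leaving out matured 1, matured 3, pre-matured 1 or pre-matured 2 gave adjusted p of 0.0791, 0.0597, 0.0643 and 0.0883. No other list passed camera with a preset correlation, with adjusted p from 0.298 to 0.965.

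**Figure D3:**
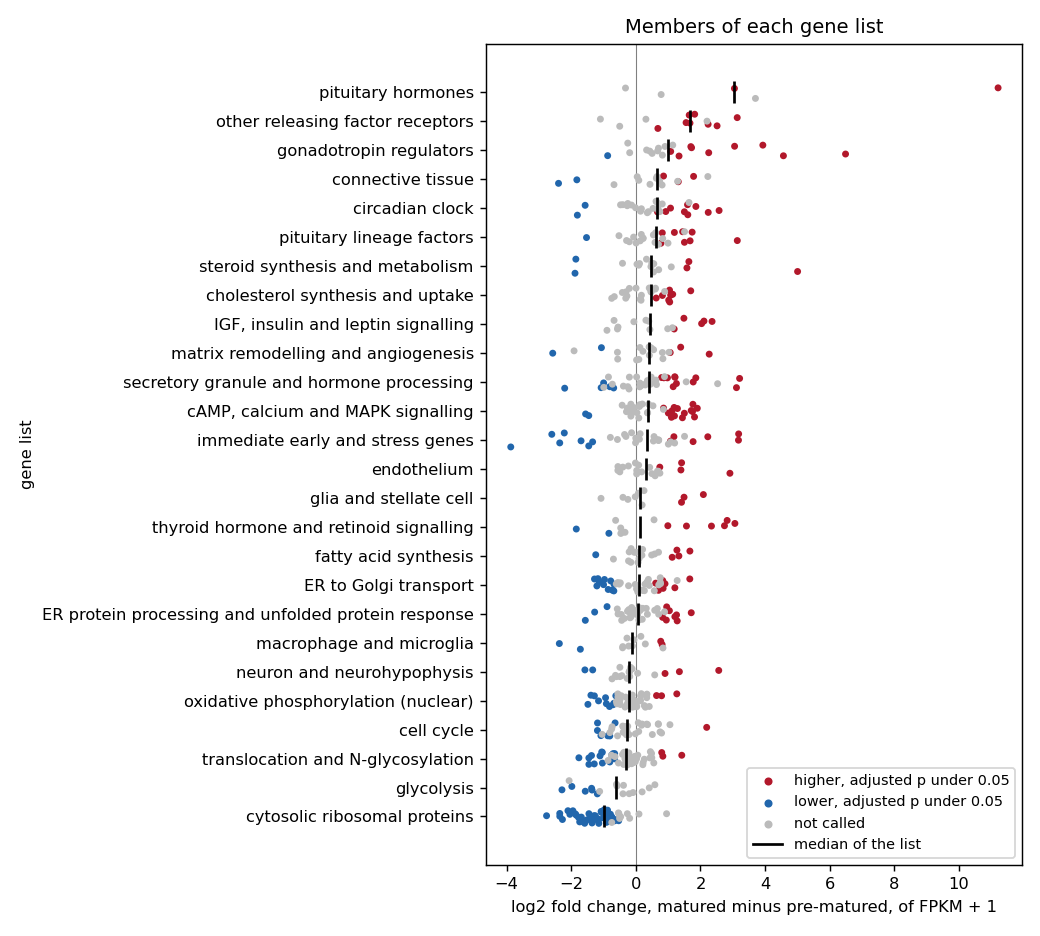
Log2 fold changes, matured minus pre-matured, of the tested members of each gene list with 5 or more members. Points are genes, coloured by whether limma called them, and black lines are list medians; the ribosomal protein list has the lowest median, -0.99, with FPKM as deposited.

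Immediate early and stress genes went both ways, with 6 of 32 higher and 7 lower, or 7 and 7 adjusted over the list alone. With TPM 9 rose and 5 fell, without genes above 1% 9 and 6, and with voom 4 and 7; leaving out 1 library gave 4 to 7 higher and 5 to 7 lower. Their median and mean log2 fold change, 0.34 and 0.12, lay above 0 while camera pointed down (adjusted p = 0.522). Besides fosl1a, atf3 and the corticosteroid-inducible kinase gene sgk1 fell with log2 fold changes of -2.60 and -2.35. In cAMP, calcium and MAPK signalling 15 of 38 rose and 2 fell, the same adjusted over the list alone, among them the phosphodiesterase gene pde4a (log2 fold change 1.90) and the transcription factor gene creb1b (1.71), as well as the kinase gene mapk8b (limma adjusted p = 0.00351). In thyroid hormone and retinoid signalling 6 of 14 rose and 2 fell, the same adjusted over the list alone; with TPM 1 fell, and with voom 3 fell. The thyroid hormone receptor gene thrb rose from 4.46 ± 1.54 to 35.4 ± 8.86 FPKM, the retinoic acid synthesis gene aldh1a2 from 0.713 ± 0.293 to 14.4 ± 7.38 FPKM and the deiodinase gene dio3a from 0.839 ± 0.685 to 8.22 ± 2.92 FPKM (SD, n = 3; limma adjusted p = 0.000902, 0.00142 and 0.00331). In IGF, insulin and leptin signalling 5 of 15 rose and 0 fell, the same adjusted over the list alone, with irs2b, igf1ra and insrb at log2 fold changes of 2.36, 1.49 and 1.19; with quantile normalization 5 rose and 3 fell, and without genes above 1% 8 and 0. Of 29 circadian clock genes 9 rose and 2 fell, the same adjusted over the list alone, with hlfa, csnk1db and rorca at 2.58, 2.24 and 1.60. Of the 25 clock genes still tested without matured 1, 2 and 3, 3, 4 and 5 rose. With quantile normalization 5 clock genes rose, and without genes above 1% 13. In matrix remodelling and angiogenesis 3 of 20 rose and 2 fell, the same adjusted over the list alone. Without any 1 of the matured libraries 1 rose and 0 fell, without pre-matured 1, 2 rose and 4 fell, without pre-matured 2, 3 rose and 1 fell, and without pre-matured 3, 1 rose and 1 fell. With quantile normalization 1 rose and 4 fell, and with TPM 5 and 1. Serpinh1a and tgfb3 rose with 1.39 and 2.27, and ccn2a fell with -2.57. Leaving out matured 1 or matured 3 ended the calls of tgfb3 (limma adjusted p = 0.0744 and 0.102) and ccn2a (0.0874 and 0.0664). Calls also ended without pre-matured 1 or 3 for tgfb3 (0.0889 and 0.0582) and without matured 2 or pre-matured 2 for ccn2a (0.0772 and 0.0599), by limma adjusted p. Tgfb3 was also not called with no filter, quantile normalization or voom (adjusted p = 0.0511, 0.0545 and 0.0813). Lower counts of 2 became 1 for cAMP, calcium and MAPK signalling without matured 3, for thyroid hormone and retinoid signalling without matured 1, matured 3 or pre-matured 3, and for the clock without any 1 of the pre-matured libraries.

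Markers of other cell types changed in both directions, and no marker list tested by camera with a preset correlation passed. Among all genes with a symbol 21.9% were higher and 10.6% lower, and several counts below, such as that of higher endothelial markers, lie near these shares. Endothelial markers rose in 4 of 20 cases and fell in 0, led by plvapb, from 2.99 ± 1.68 to 27.8 ± 5.24 FPKM, with esamb and sox17 at log2 fold changes of 1.42 and 1.39 (SD, n = 3; limma adjusted p = 0.000947, 0.0123 and 0.0140). Without any 1 of the matured libraries 1 of the 16 endothelial markers still tested rose, and esamb and sox17 were not past the filter. With quantile normalization and voom 2 rose and 1 fell, and without genes above 1% 7 rose. With voom esamb and sox17 lost their calls (adjusted p = 0.0601 and 0.0597, log2 fold change 3.60 and 3.28), as did sox17 with quantile normalization (adjusted p = 0.0752). Of 15 connective tissue markers 3 rose and 2 fell, or 4 and 2 adjusted over the list alone: twist1b and pdgfra rose with 1.31 and 1.79, and the smooth muscle gene tagln fell from 409 ± 14.1 to 78.7 ± 19.4 FPKM (SD, n = 3; limma adjusted p = 0.000872). With TPM 5 connective tissue markers rose and 2 fell, and without genes above 1% 5 and 1. Without matured 1 or 2, 1 rose, and 1 fell without matured 1, matured 2, pre-matured 1 or pre-matured 3. Of 10 glia and stellate cell markers 3 rose and 0 fell, namely ndrg2, cldn11a and slc1a3a, with log2 fold changes of 1.41, 2.09 and 1.49. The call of slc1a3a was lost without matured 1, matured 3 or pre-matured 1 (limma adjusted p = 0.085, 0.070 and 0.0562) and with voom (0.0502). Of 21 neuron and neurohypophysis markers 3 rose and 2 fell, with mapta and nefma at 1.35 and 2.56 and stmn2b at -1.58, and 1 fell without matured 1, matured 3, pre-matured 2 or pre-matured 3 and with TPM. Of 13 macrophage and microglia markers 2 rose and 2 fell, with ncf1 and apoeb at -1.72 and -2.37 and c1qc at 0.81. No macrophage marker was higher without matured 1, matured 2 or pre-matured 1, nor with median-ratio scaling or voom. Without matured 1, 2 or 3 the calls of apoeb (limma adjusted p = 0.0704, 0.0903 and 0.0601) and c1qc (0.066, 0.115 and 0.101) were lost, as they were without pre-matured 2 (0.0553 and 0.0577), and that of c1qc without pre-matured 1 (0.0797). C1qc was also not called with no filter, median-ratio scaling or voom (adjusted p = 0.0635, 0.0647 and 0.0991). The erythrocyte marker alas2 fell (log2 fold change -2.46, limma adjusted p = 0.0396), stood at 76.6 FPKM in pre-matured 1 against 7.12 and 14.97 FPKM in pre-matured 2 and 3, and was not called without any 1 of the matured libraries (limma adjusted p between 0.103 and 0.132) or without pre-matured 3 (0.051), nor with no filter or voom (0.0618 and 0.107). Epb41b and cahz did not pass (limma adjusted p = 0.141 and 0.825), though epb41b did with quantile normalization, median-ratio scaling and voom (0.0422, 0.0386 and 0.0316). Of 4 cartilage and bone markers ctsk rose (0.90; limma adjusted p = 0.0578 without matured 2), while sox9a and col9a1a did not pass, and of 3 liver markers hp fell (-1.95), while tfa and rbp4 did not. Hp was not past the filter, and so not tested, when any 1 of the pre-matured libraries was left out. None of the 3 lymphocyte, 2 skeletal muscle and 2 gonad markers tested by limma was called, with 1 skeletal muscle marker higher adjusted over the list alone. With quantile normalization 2 lymphocyte markers and 1 gonad marker were lower. The skeletal muscle list had 1 higher marker with TPM, without genes above 1%, with a length trend removed and without matured 3 or pre-matured 3, and the lymphocyte list 1 without matured 3. The median of the lymphocyte markers was -0.33 and their mean 0.19. Counts for the other marker lists were the same adjusted over the list alone.

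The highest mean FPKM over all libraries belonged to LOC118234779, gh1, ND2, scg3 and rplp1. LOC118234779 fell from 41066 ± 12750 to 5727 ± 1703 FPKM (SD, n = 3; limma adjusted p = 0.00108) and took 8.43%, 4.55% and 8.30% of the reads of the pre-matured libraries. The mitochondrial gene ND2 and the ribosomal protein gene rplp1 fell with log2 fold changes of -0.86 and -0.88 (limma adjusted p = 0.0400 and 0.0160). ND2 lost its call with TPM, no filter, totals taken without genes above 1% and a length trend removed (adjusted p = 0.0963, 0.0766, 0.144 and 0.171), and when any library but pre-matured 2 was left out, with limma adjusted p between 0.0624 and 0.127. Rplp1 lost its call without matured 2 and with a length trend removed (limma adjusted p = 0.0532 and 0.0828). The largest rises without a symbol were of LOC118216345, at 847, 587 and 1229 FPKM in matured libraries against 0.0535 FPKM in pre-matured 2 and a listed 0 in pre-matured 1 and 3, and of LOC118231679, from 0.729 ± 0.386 to 620 ± 365 FPKM (SD, n = 3; limma adjusted p = 2.28e-06 and 0.000284); both were chosen after their values were seen. The table does not pair these identifiers with gene names. It is given per gene, so changes in the share of single transcripts are not analysed here.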

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

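No paired analysis was possible because replicate numbers follow accession order only. Median-ratio scaling, voom, the length correction and the ribosomal list with kinases were chosen after seeing the data; other alternatives were planned. Alternatives meant for counts, and for transcripts, were not run. The cause of each shift was not tested, except where fewer genes or libraries entered.

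The 5981 changed genes (4184 higher, 1797 lower) became 2672 (1928 and 744) at adjusted p under 0.01. Higher genes numbered 2714 with the stricter filter, which tests fewer genes. Lower genes numbered 1116 with a fold of at least 2, 2896 with quantile normalization, 978 with TPM, 1041 without genes above 1% and 2727 with median-ratio scaling. Leaving out 1 library gave 2900 to 5332 changed, 1942 to 3954 higher and 958 to 1553 lower genes, lowest without matured 1. Of the 4184 higher and 1797 lower calls, TPM kept 4184 and 978, and quantile normalization 2875 and 1726. Of genes called both with and without a scaling change, 4601 of 4602 kept their direction with quantile normalization and 5162 of 5162 with TPM. A call in both settings makes the same direction likely, so this is no check of the calls.

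The 7 lists became 0 with an estimated correlation, 11 with fry, which tests each list alone, and 4 with the length trend removed; leaving out 1 library gave 5 to 7. The translocation median turned to 0.033 with TPM and 0.036 without genes above 1%, and the oxidative phosphorylation median to 0.10, 0.11 and, with the length trend removed, 0.095. With TPM and without genes above 1% all genes move up, and both lists stayed below the median of all genes and passed camera; with the length trend removed oxidative phosphorylation did not pass. The mean correlation within minus between groups, 0.125, was 0.523 over the 500 most variable genes and 0.181 with the stricter filter.

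The filter of 3 libraries left 95 of the 111 named genes tested without a matured library and 106 without a pre-matured one, so genes near 0 in a group have no such check. None of the 102 named genes called reversed where tested; voom lost 11 and the other settings 0 to 9. Genes not called reversed: fshb (-1.66 to 2.38 over the left-out libraries), pomca (-0.60 to 0.034), rbp4 (-1.54 to 0.58) and cahz (-0.30 to 0.43; -0.20 with quantile normalization, -0.071 with median-ratio scaling, -0.14 with voom). Depth limits weak genes: lhb rests on 10 and 7 reads in pre-matured 1 and 2.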

Other observations

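All tests in this part were chosen after the result they bear on was seen, except the split of libraries for gene lists and the test of hypoxia-inducible genes, which were written before their results.

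Beyond the fixed lists, 86 families of genes sharing a symbol stem, with 12 or more tested members, were compared by camera with a preset correlation. The families rpl and rps, with 41 and 29 tested members, are not the ribosomal list of 62. They can hold kinases and ribosomal protein-like genes removed from that list, and 1 rps member was higher where the list had 0. Besides rpl and rps (adjusted p = 7.17e-21 and 4.49e-06), translation initiation factors (eif: 16 of 47 lower, 3 higher, adjusted p = 0.000115) and mitochondrial ribosomal proteins of the large subunit (mrpl: 10 of 46 lower, 4 higher, adjusted p = 0.0165) passed, while with an estimated correlation the adjusted p was 0.654 for eif and 0.963 for rpl, rps and mrpl. The medians of eif and mrpl lay -0.55 and -0.50 from that of all genes, and -0.53 and -0.51 with TPM, where the medians themselves, -0.31 and -0.27 with FPKM, were 0.01 and 0.03. With quantile normalization these gaps were -0.31 and -0.45, and those of rpl and rps were -0.48 and -0.12, against -1.21 and -0.97 with FPKM. Adaptor protein genes (ap, 11 of 25 higher), myotubularins (mtmr, 7 of 12) and syntaxins (stx, 7 of 12) had 0 lower members but did not pass (adjusted p = 0.0861, 0.0861 and 0.158). Of 332 genes with a Novelgene identifier 117 were higher and 69 lower by limma, 35.2% and 20.8%, against 24.9% and 8.79% of genes with a LOC identifier and 21.9% and 10.6% of genes with a symbol.

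The real split of the 6 libraries called 5981 genes by limma and the other 9 of the 10 splits called 0, with 228 to 388 genes at an unadjusted p under 0.05 against 8084 in the real split. For gene lists by camera with a preset correlation, the real split passed 7 and the highest other split also 7, so 2 of 10 splits gave as many lists and 1 of 10 as many genes. With 10 splits, a share under 0.05 cannot be reached. Each of the other 9 splits also mixes matured and pre-matured libraries on both sides. The difference between the groups then adds to the spread within each side, which lowers the count of genes. The other splits thus cannot show how many genes or lists would differ by chance.

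The fall of ribosomal protein genes was weighed against gene length and scale. Their median log2 fold change lay 0.84 below that of 436 other genes picked for similar length (-0.838, bootstrap SE 0.0995). The match was not exact: median length was 664 bases in these genes and 584.5 in ribosomal protein genes. Log2 fold change rose weakly with length (Spearman rho 0.17), so the gap may be somewhat too wide. The SE of this gap comes from resampling genes and not libraries, so it leaves out the spread between samples. Of the 52 genes called lower, 36 were still called after a length trend was removed. Both values argue against length as the whole cause of the fall. A part of it went with length: the median went from -0.99 to -0.63 after that correction. A few abundant genes that shift the scale are opposed, since 1 factor per library moves all genes alike, and ribosomal protein genes lay apart. The gap to the median of all tested genes was -1.16 (bootstrap SE 0.0870) or further from 0 in the 5 scalings of that kind. These scalings are not separate checks, since such a factor hardly changes the gap. An earlier bound that also counted quantile normalization, which is no such factor, was replaced. With quantile normalization the gap was -0.321 (SE 0.156), so a distortion that depends on expression level stays open, as does a change in ribosome production with maturation, which was not tested.

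Pre-matured 3 held 518 lhb reads, against 10 and 7 in the other pre-matured libraries. Carry-over from a matured library would bring its other abundant transcripts. From matured 1 or matured 3 it is opposed by at least 2 genes whose reads lay below the Bonferroni-adjusted Poisson 5% point: gnrhr4 (38.6 and 41.2 reads predicted) and LOC118216345 (34.3 and 60.1 predicted) had 0 reads in pre-matured 3. Carry-over from matured 2 cannot be told apart, since 1 gene, LOC118216345 (54.8 reads predicted, 0 found), speaks against it among 614 genes. That bound was set after the values were seen and replaced one that ignored the number of genes. Expression of lhb in that pituitary itself stays open and was not tested.

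Matured 2 had fshb at 514 FPKM against 4.44 and 0.899 in matured 1 and 3, and gnrhr4 at 14.5 against 287 and 254. A mixture with, or exchange for, 1 of the 3 pre-matured libraries here is opposed by fshb, which lay 24.3-fold above its highest level in them. A mixture with a pituitary outside these libraries is not covered by this. A lower share of all gonadotropes is opposed by fshb at 193-fold the mean of matured 1 and 3 while gnrhr4 was 18.6-fold lower. Both points rest on the fshb value that set matured 2 apart, in 1 library, so they are not separate checks. A different balance of cells making lhb and fshb stays open. In the number of genes apart, matured 2 lay within the range of the other libraries: 91 genes lay 4-fold or more from both other libraries of its group, against 48 and 56 for matured 1 and 3 and 89 to 115 for pre-matured libraries.

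As a hypothesis, lower glycolysis genes in matured pituitaries may go with lower hypoxia-inducible genes. Among 30 such genes in no other list, 6 were higher and 6 lower by limma, and camera with a preset correlation gave p = 0.243, with members such as ankrd37, ddit4 and egln3 lower and pdk1, ak4 and bnip3la higher. The test did not pass; as members went both ways, it neither bears the hypothesis out nor excludes it, and the bound written beforehand, which took a missed threshold as exclusion, was wrong in that.

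The mitochondrial gene ND2 stood at 5882 to 17933 FPKM and ND3 at 14.2 to 59.0 FPKM, while COX1, COX2, COX3 and CYTB are listed at 0 in all 6 libraries. Of 8 hormone genes matched, prl, prl2 and tshba were at 1.01 FPKM or less in every library. Genes with a LOC identifier could not be matched by symbol. A copy of these genes or of pomca under such an identifier is thus not counted here.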
